A study of Homo sapiens with 8 samples.

How the data were processed

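RNA-seq was carried out on total RNA of HepG2 WT and p53 KO cells, without treatment or after 24 h of ADR at 500 ng/mL, as paired-end, strand-specific libraries of 150 bases sequenced on an Illumina instrument, per the labels' protocols. The 8 libraries fall into 4 groups of 2, and the labels call the samples of a group independent. Reads were aligned with HISAT2 2.0.5 at default settings to hg19, per the series' design text, and hg38 is named for the untreated KO samples in the submitters' processing notes. The counting tool, the annotation and the use of strand in counting are not given in the sources used here, which matters for antisense, overlapping and near-identical genes.

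The files hold the authors' DESeq2 result tables, per the submitters' processing notes and the file headers, for 3 comparisons: WT ADR against WT untreated, KO ADR against WT ADR, and KO ADR against KO untreated. Each deposited table gives a signal per gene, the mean over libraries of read counts divided by size factors. It also gives the authors' log2 fold change with its standard error in log2 units, a score that is the Wald statistic of the authors, and the authors' p-value and adjusted p-value. Checked on the values, the statistic equals the fold over its standard error, the p-value is its normal p, and the adjusted p equals a Benjamini-Hochberg adjustment over the genes that have one, each within 1e-06. The tables of WT response and of KO against WT list 57820 genes with identical means, so they come from 1 fit, in which 12251 genes are listed at a mean of 0. The table of KO response lists 46950 genes, and 42624 identifiers without version are shared. The highest standard error is 0.862 in the first fit and 5.00 in the second, so folds of low genes were moderated by a prior in the first fit only. Genes without an adjusted p in the authors' table were left out of counts, never set to 1.

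Per-gene tests on counts had been planned before the data were examined, but the tables analysed here hold no value per library. The main results are therefore the authors' deposited adjusted p under 0.05, within each table. The planned fits on counts, their alternatives, the replicate block and the omission of single libraries were not run. The depth of each library was read from genes whose mean is that of 1 read in 1 library: these means fall on 8 steps in each fit, whose size factors run from 0.842 to 1.23. The steps were assigned to groups by the sign of the folds, and those of the untreated KO group by elimination.

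The difference between the WT and KO responses was computed for genes with an adjusted p in both fits. These also had a mean of at least 100 in the fit of the WT response, with no minimum on the mean in the fit of the KO response. The statistic was the difference of the deposited folds over the root of the summed squared standard errors. It was given a 2-sided normal p and Benjamini-Hochberg adjustment. That minimum was chosen after the standard errors of both fits were seen. On simulated data for this step (11837 genes) 25% of genes with a true difference of 1 and 90% of those with 2 were recovered, of 100 each, and 6 unchanged genes were called. Genes that rose in WT and were lower in treated KO cells were counted among those tested in both tables, beside the count for independent lists and 100 simulations of unchanged groups sharing the treated WT libraries. lncRNAs are genes of the types lincRNA, antisense, sense intronic, sense overlapping and processed transcript, from the gene type given in the authors' deposited tables.

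The 18 gene lists, fixed before the data were examined, were p53 target genes, p53-linked lncRNAs, mitosis and G2/M, DNA replication and S phase, replication-dependent histones, the BCL2 family, hepatocyte genes, cholesterol synthesis, NF-kB and cytokines, interferon-stimulated genes, the unfolded protein and integrated stress response, immediate early genes, NRF2 targets, ribosomal proteins, mitochondrially encoded genes, and fibroblast, leukocyte and endothelial markers. They were written from general knowledge, not from these samples, and hold 383 distinct genes. Each was tested with cameraPR of limma 3.58.1 (R 4.3.3) on the authors' deposited statistics, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over lists. A correlation could not be estimated without values per library, so presets of 0.05 and 0.1 were used in its place. In 100 simulated draws of statistics independent between genes, the set test found 99 shifted and 6 unshifted sets. Correlated genes were not simulated, so these draws do not give the error rate of the test in these data.

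Named genes follow a rule fixed before the data were examined: TP53, CDKN1A and MDM2, the 8 largest rises and falls per comparison at or above the median tested mean, and up to 4 members per list. It adds the 8 lncRNAs with the largest rise and the 6 largest differences of response in each direction, not all of which are printed. The part of the rule that asked for no overlap between libraries could not be applied, and exceptions are marked in the text. Gene coordinates and GC content came from the GENCODE 44 annotation mapped to GRCh37, and no coordinates were converted between builds. Alternatives tried were a stricter threshold, other filters on the mean, centring of folds on the median expressed gene, a correction for GC content (lowess, fraction 0.3), a test on ranks, higher correlations and larger standard errors. Scripts ran under Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.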

Results

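Gene expression was measured by RNA-seq in HepG2, an established human liver cancer cell line with wild-type p53 (WT), and in HepG2 cells with a p53 knockout (KO), each without treatment or after 24 h of ADR at 500 ng/mL. The labels do not expand ADR, which in work on p53 is the usual abbreviation of adriamycin (doxorubicin), a drug that damages DNA. The 8 libraries formed 4 groups of 2 independent samples, and 3 comparisons of these groups were analysed, each from the authors' deposited table. Those tables give, per gene, a mean normalised read count over libraries, a log2 fold change with its standard error (SE) and an adjusted p, with no value per library. Size factors read from genes with 1 read in all libraries together ran from 0.842 to 1.23, so the libraries had similar depth. The 2 libraries per group limit the precision: the median SE of the WT response was 0.24 at a mean normalised count above 1000 and 0.83 at a mean between 1 and 10. For the KO response, whose folds were not moderated by a prior as those of the WT response were, the median SE was 0.24 and 2.10.

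TP53 (ENSG00000141510.11; chromosome 17, 7565097 to 7590856 in GRCh37), which encodes p53 and is the knocked-out gene, was still listed with a mean normalised count of 1609.5 in the authors' deposited table. Its transcript was lower in treated KO than in treated WT cells, with a log2 fold change of -1.80 (SE 0.23, adjusted p 1.4e-13) in the authors' deposited table. Its WT response was -0.0021 (SE 0.23, adjusted p 0.997) and its KO response 0.70 (SE 0.23, adjusted p 0.0175) in the authors' deposited tables. A value per library could not be given, and an edit can end the protein while its transcript remains, so the transcript checks the labels only in part.

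The response of WT cells to ADR addressed which transcripts the drug changes in the presence of p53. The p53 target genes rose as a group: 50 of 59 tested members rose, 1 fell and 8 did not pass (52 and 2 adjusted over the list alone). Their median log2 fold change was 1.80 in the authors' deposited table, with a set test adjusted p of 6.55e-43. CDKN1A, the cyclin-dependent kinase inhibitor p21 (ENSG00000124762.9; chromosome 6, 36644237 to 36655114 in GRCh37), rose by 2.90 (SE 0.25, adjusted p 6.93e-29) in the authors' deposited table. MDM2, the ubiquitin ligase that degrades p53, rose by 2.27 (SE 0.23, adjusted p 2.52e-20), and TP53I3, a quinone oxidoreductase, by 5.20 (SE 0.25, adjusted p 4.03e-95), in the same table of the authors. The exception that fell, named after its value was seen, was the decoy death receptor TNFRSF10C, at -0.86 (SE 0.35, adjusted p 0.0425) in the authors' deposited table. CCNG1, the most abundant target that did not pass, had 0.28 (SE 0.26, adjusted p 0.451) there. Of 12 tested p53-linked lncRNAs, 9 rose and 0 fell (9 and 0 adjusted over the list alone), with a set test adjusted p of 2.71e-08. Among them were PINCR (listed as RP3-326I13.1), at 5.77 (SE 0.36), LINC00324, at 4.28 (SE 0.37), and the nuclear paraspeckle RNA NEAT1, at 1.81 (SE 0.20), in the authors' deposited table.

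Genes of DNA replication fell in WT cells: 24 of 34 members fell, 3 rose and 7 did not pass (25 and 4 adjusted over the list alone), with a set test adjusted p of 4.45e-11. UHRF1, which maintains DNA methylation at replication forks, had a log2 fold change of -4.07 (SE 0.26), and the replicative helicase subunits MCM6 and MCM3 had -2.72 (SE 0.22) and -2.19 (SE 0.22), in the authors' deposited table. The members that rose were the sliding clamp PCNA (1.59, SE 0.22), the ribonucleotide reductase subunit RRM1 (0.94, SE 0.24) and thymidylate synthase TYMS (0.51, SE 0.21), in the authors' deposited table. PCNA, RRM1 and TYMS were named after their values were seen. All 14 replication-dependent histone genes fell (14 adjusted over the list alone, set test adjusted p 9.65e-13), such as HIST1H2BC at -2.69 (SE 0.29) in the authors' deposited table. Reads of near-identical histone copies make single members uncertain. Of 20 cholesterol synthesis genes, 18 fell and 0 rose (18 and 0 adjusted over the list alone, set test adjusted p 1.43e-20). They included squalene epoxidase SQLE (-2.83, SE 0.22) and DHCR7 (-2.93, SE 0.27), while DHCR24 had -0.018 (SE 0.24, adjusted p 0.968), in the authors' deposited table. Hepatocyte genes fell in 18 of 32 cases and rose in 1 (19 and 1 adjusted over the list alone, set test adjusted p 1.30e-08). Haptoglobin HP had -3.16 (SE 0.29), the asialoglycoprotein receptor ASGR1 -2.27 (SE 0.28) and apolipoprotein APOB -0.40 (SE 0.27, adjusted p 0.263), in the authors' deposited table.

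In the unfolded protein and integrated stress response list, 11 of 23 members fell and 2 rose in WT cells (12 and 2 adjusted over the list alone, set test adjusted p 6.87e-08). The serine synthesis enzyme PHGDH, at -4.40 (SE 0.27), and the cystine transporter SLC7A11, at -3.72 (SE 0.28), led it in the authors' deposited table. The members that rose, SESN2 (1.77, SE 0.27) and ATF3 (0.91, SE 0.27), also belong to the p53 target list, per the authors' deposited table for the values. SESN2 and ATF3 were named after their values were seen. Of 16 NRF2 targets, 9 fell and 1 rose (10 and 1 adjusted over the list alone, set test adjusted p 5.30e-07). Among them were the aldo-keto reductases AKR1C2 (-2.13, SE 0.22) and AKR1C1 (-2.01, SE 0.22), in the authors' deposited table. These are near-identical paralogs, so the split of reads between them is uncertain. Ribosomal protein genes fell in 15 of 37 cases and rose in 0 (17 and 0 adjusted over the list alone, set test adjusted p 4.03e-05). The set test did not pass for mitosis and G2/M genes (2 rose, 7 fell of 30, adjusted p 0.0717), or immediate early genes (8 rose, 2 fell of 16, adjusted p 0.0717). The BCL2 family (5 rose, 2 fell of 15, adjusted p 0.322) and interferon-stimulated genes (5 rose, 3 fell of 19, adjusted p 0.375) did not pass it. Nor did it pass for mitochondrially encoded genes (2 rose, 0 fell of 13, adjusted p 0.245) or NF-kB and cytokine genes (4 rose, 2 fell of 14, adjusted p 0.717). EGR1, an immediate early transcription factor, rose by 2.48 (SE 0.27), MYC had -1.98 (SE 0.25) and the BH3-only gene PMAIP1 rose by 2.53 (SE 0.26), in the authors' deposited table.

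Leukocyte markers rose in 3 of 8 cases and fell in 1 (5 and 1 adjusted over the list alone, set test adjusted p 0.0499, and adjusted p = 0.0885 with a correlation preset to 0.05). Endothelial markers rose in 3 of 6 cases (3 adjusted over the list alone, set test adjusted p 0.0391, and adjusted p = 0.0638 with a correlation preset to 0.05). The median mean normalised count was 29.0 over leukocyte and 8.22 over endothelial markers, with median log2 fold changes of 1.28 and 1.88. Protein-coding genes with a mean of 2 to 50 had a median of 1.47 in WT, and 1734 of 4543 rose. The set test compares with genes of all means, so both calls cannot be told apart from that rise of genes with low means. VWF, von Willebrand factor, rose by 7.05 (SE 0.52) at a mean normalised count of 160.9, and CSF1R by 5.95 (SE 0.58) at a mean of 62.2, in the authors' deposited table. The leukocyte marker LYZ, lysozyme, had 0.63 (SE 0.27, adjusted p 0.0597) at a mean of 69989.5 in the authors' deposited table. Fibroblast markers fell in 1 of 9 cases (PDGFRB, -2.44, SE 0.25, in the authors' deposited table; set test adjusted p 0.743). For this list the median (0.78) and the mean (0.51) lay above 0 and the set test pointed down, and for NF-kB genes the median was -0.036 and the mean 0.28.

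Over all genes, 5300 rose and 3587 fell among 27278 tested in WT cells at an adjusted p under 0.05 in the authors' deposited table. Of these, 4487 and 2012 changed by 1 or more on the log2 scale. At a mean of at least 100, 5549 genes changed. The largest rises among genes at or above the median mean included those of TREM2, a lipid receptor of myeloid cells (9.34, SE 0.41), and PADI4, a peptidylarginine deiminase (9.30, SE 0.46), in the authors' deposited table. They also included those of CSTA, the protease inhibitor cystatin A (9.21, SE 0.34), and MUC2, a secreted mucin (9.08, SE 0.50), in the authors' deposited table. The largest falls included ATP1A2 (-4.45, SE 0.36), the metallothionein MT1G (-4.33, SE 0.37), the fatty acid binding protein FABP1 (-4.26, SE 0.26) and PCSK9 (-4.09, SE 0.29), in the authors' deposited table. The median gene with a mean of at least 100 lay at -0.143 in this comparison, at 0.0775 in KO against WT and at -0.102 in the KO response. The split of calls moved with the scaling and, in the other direction, with the filter on the mean. Of changed genes, 59.6% rose as deposited, 69.3% after folds were centred on the median gene and 71.3% after a correction for GC content. Among genes at or above the median mean 42.9% rose. At a mean of at least 100 the share was 39.8%, with 2207 genes that rose and 3342 that fell.

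**Figure D1:**
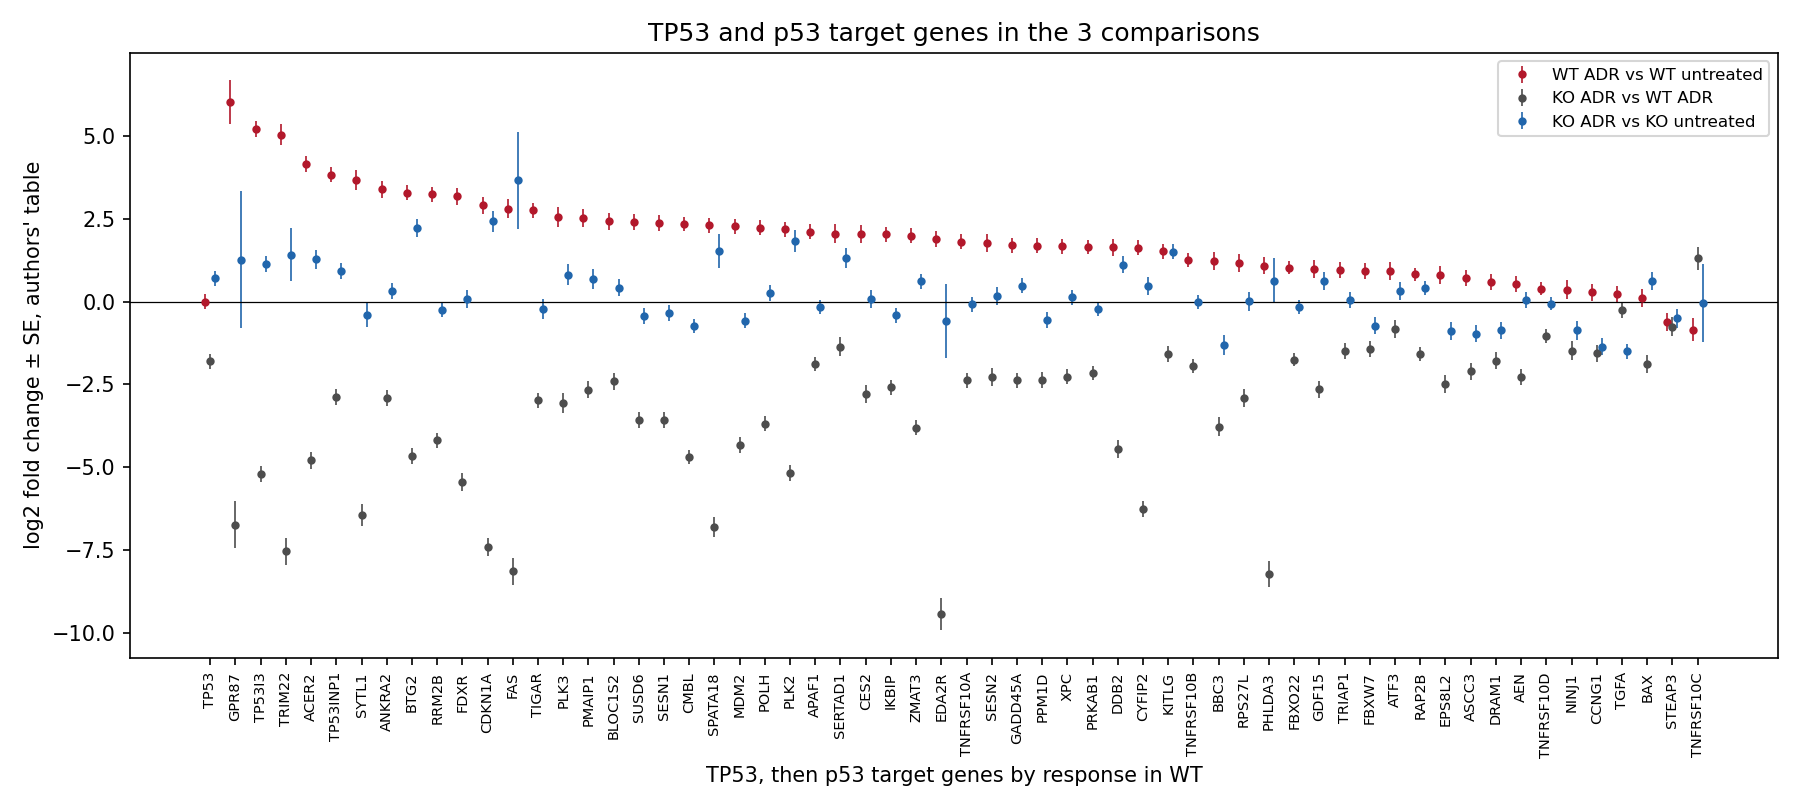
Log2 fold change (points) and SE (bars) of TP53 and the p53 target genes in the authors' deposited tables, ordered by the WT response, for WT response (red), KO against WT under ADR (grey) and KO response (blue). In the WT response 50 of 59 targets rose, and 57 of 59 were lower in treated KO cells.

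The comparison of treated KO with treated WT cells addressed what the loss of p53 changes under the drug. Of 59 p53 target genes, 57 were lower in KO cells and 1 was higher (57 and 1 adjusted over the list alone). The median log2 fold change was -2.66 in the authors' deposited table, with a set test adjusted p of 1.73e-129. CDKN1A was lower by a log2 fold change of -7.41 (SE 0.26, adjusted p 5.79e-176), SPATA18, of mitochondrial quality control, by -6.81 (SE 0.30) and CYFIP2 by -6.27 (SE 0.25), in the authors' deposited table. MDM2 had -4.33 (SE 0.24, adjusted p 3.73e-73), and the target that did not pass was the growth factor TGFA, at -0.25 (SE 0.23, adjusted p 0.507), in the authors' deposited table. The target that was higher, again TNFRSF10C, had 1.31 (SE 0.34, adjusted p 0.00101) in the authors' deposited table. Of 12 p53-linked lncRNAs, 7 were lower and 0 higher (7 and 1 adjusted over the list alone, set test adjusted p 4.63e-13). PURPL (listed as LINC01021) had -5.25 (SE 0.26) in the authors' deposited table.

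DNA replication genes were higher in treated KO cells: 27 of 34 were higher and 2 lower (28 and 2 adjusted over the list alone, set test adjusted p 1.51e-21). UHRF1 was higher by 4.73 (SE 0.26), the cell cycle transcription factor E2F1 by 3.84 (SE 0.29) and MCM6 by 2.61 (SE 0.22), in the authors' deposited table. PCNA (-1.09, SE 0.22) and TYMS (-0.74, SE 0.21), again named after their values were seen, were lower, in the authors' deposited table. Cholesterol synthesis genes were higher in 13 of 19 cases and lower in 0 (17 and 0 adjusted over the list alone, set test adjusted p 9.34e-08), such as SQLE, at 1.71 (SE 0.22) in the authors' deposited table. Hepatocyte genes were higher in 17 of 32 cases and lower in 1 (19 and 1 adjusted over the list alone, set test adjusted p 2.32e-05). APOC3 had 2.81 (SE 0.33) and the transthyretin gene TTR 1.93 (SE 0.24), and albumin, ALB, was the member that was lower, at -3.58 (SE 0.31), in the authors' deposited table. NF-kB and cytokine genes were higher in 8 of 14 cases and lower in 0 (8 and 0 adjusted over the list alone, set test adjusted p 0.000177). The apoptosis inhibitor BIRC3 was at 2.70 (SE 0.31) and CCL20 at 1.80 (SE 0.26) in the authors' deposited table. Interferon-stimulated genes were higher in 9 of 19 cases and lower in 1 (9 and 1 adjusted over the list alone, set test adjusted p 0.0431, and adjusted p = 0.144 with a correlation preset to 0.05). The member that was lower was the transcription factor STAT1, at -1.05 (SE 0.20) in the authors' deposited table.

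The set test did not pass for the BCL2 family (2 higher, 6 lower of 15, adjusted p 0.0533). In that family the BH3-only gene BBC3 had -3.78 (SE 0.29), BAX -1.88 (SE 0.27) and MCL1 -0.016 (SE 0.22, adjusted p 0.975) in the authors' deposited table. It did not pass for mitosis and G2/M genes (9 higher, 3 lower of 30, adjusted p 0.0542), ribosomal protein genes (0 higher, 1 lower of 37, adjusted p 0.101) or mitochondrially encoded genes (0 higher, 0 lower of 13, adjusted p 0.806). The same held for the stress response list (4 higher, 6 lower of 23, adjusted p 0.666), immediate early genes (4 higher, 3 lower of 16, adjusted p 0.684) and NRF2 targets (2 higher, 4 lower of 16, adjusted p 0.905). Histone genes split into 4 higher and 2 lower of 14 (adjusted p 0.986), with HIST1H2BK at -4.60 (SE 0.31) and HIST1H4C at 1.59 (SE 0.31) in the authors' deposited table. The median of that list was 0.18 and its mean -0.052, and for NRF2 targets the median was -0.0099 and the mean 0.034. Fibroblast markers (2 higher, 1 lower of 9, adjusted p 0.324, median -0.16, mean 0.27) did not pass either. Nor did leukocyte markers (1 higher, 2 lower of 8, adjusted p 0.324) or endothelial markers (0 higher, 1 lower of 6, adjusted p 0.375, median 0.060, mean -0.39).

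Over all genes, 3142 were higher and 3557 lower in treated KO cells among 26407 tested, from the authors' deposited table. Of the changed genes, 46.9% were higher as deposited and 40.8% after folds were centred on the median gene, while 51.4% were higher among genes at or above the median mean and 52.5% at a mean of at least 100. The largest differences downward included those of TREM2 (-10.53, SE 0.50), CSTA (-10.15, SE 0.38) and the ectodysplasin receptor EDA2R (-9.43, SE 0.48), in the authors' deposited table. The largest differences upward included those of the chemokine CXCL5 (5.85, SE 0.47), the calcium sensor SCGN (5.46, SE 0.35), the ectonucleotidase NT5E (5.01, SE 0.31) and FABP1 (4.98, SE 0.26), in the authors' deposited table.

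The response of KO cells to ADR addressed what the drug does without p53. The p53 target genes did not move as a group: 11 rose, 9 fell and 39 of 59 did not pass (13 and 10 adjusted over the list alone), with a set test adjusted p of 0.647, from the authors' deposited table. CDKN1A rose by 2.42 (SE 0.32, adjusted p 2.61e-12) and the antiproliferative gene BTG2 by 2.22 (SE 0.27), while TGFA had -1.51 (SE 0.23), BBC3 -1.31 (SE 0.31) and MDM2 -0.58 (SE 0.23, adjusted p 0.0598), in the authors' deposited table. Of 15 p53-linked lncRNAs, 2 rose and 2 fell (2 and 2 adjusted over the list alone, set test adjusted p 0.949). MIR34AHG (ENSG00000228526.7), the host of a p53-linked microRNA, rose by 2.29 (SE 0.27) and PURPL had -1.65 (SE 0.27), in the authors' deposited table. The gene taken for MIR34AHG in the other tables has another identifier (ENSG00000234546.2), so its values are not compared. That gene is counted among the p53-linked lncRNAs of those tables, and it rose in WT cells by 2.36 (SE 0.41) in the authors' deposited table.

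NF-kB and cytokine genes rose in 12 of 15 cases in KO cells and fell in 0 (12 and 0 adjusted over the list alone, set test adjusted p 3.05e-09). CXCL8, the chemokine interleukin 8, rose by 3.43 (SE 0.34), RELB, an NF-kB subunit, by 2.76 (SE 0.32) and SOD2 by 1.48 (SE 0.21), in the authors' deposited table. SOD2 had a mean normalised count over all libraries of 8283 here against 13298 in the fit of the WT response. Immediate early genes rose in 11 of 16 cases and fell in 1 (11 and 1 adjusted over the list alone, set test adjusted p 3.40e-06). EGR1 was at 3.27 (SE 0.27) and EGR3 at 5.09 (SE 0.75) in the authors' deposited table. DNA replication genes rose in 19 of 34 cases and fell in 0 (22 and 0 adjusted over the list alone, set test adjusted p 1.86e-09). They included E2F2 (2.26, SE 0.28), E2F1 (1.95, SE 0.29) and RRM2 (1.18, SE 0.20), while MCM3 had -0.047 (SE 0.22, adjusted p 0.918), in the authors' deposited table. Interferon-stimulated genes rose in 4 of 19 cases and fell in 1 (4 and 1 adjusted over the list alone, set test adjusted p 0.0396, and adjusted p = 0.116 with a correlation preset to 0.05).

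Cholesterol synthesis genes fell in 14 of 19 cases in KO cells and rose in 0 (17 and 0 adjusted over the list alone, set test adjusted p 7.63e-15). SQLE had -1.78 (SE 0.21) and mevalonate kinase MVK -1.96 (SE 0.29) in the authors' deposited table. Histone genes fell in 10 of 13 cases and rose in 0 (11 and 0 adjusted over the list alone, set test adjusted p 2.84e-10). NRF2 targets fell in 10 of 16 and rose in 1 (10 and 1 adjusted over the list alone, set test adjusted p 2.18e-12). The stress response list fell in 11 of 23 cases and rose in 1 (13 and 1 adjusted over the list alone, set test adjusted p 2.84e-10). The transcription factor ATF4 was at -1.70 (SE 0.21) and asparagine synthetase ASNS at -2.93 (SE 0.36) in the authors' deposited table. The mean normalised count of ASNS over all libraries was 142.1 here and 1437 in the fit of the WT response. Hepatocyte genes fell in 7 of 32 cases and rose in 2 (8 and 2 adjusted over the list alone, set test adjusted p 0.00316). Their adjusted p was 0.0496 with a correlation preset to 0.05 and adjusted p = 0.16 with one preset to 0.1. Among them was CEBPA, a hepatocyte transcription factor, at -1.95 (SE 0.24) in the authors' deposited table, with a mean normalised count over all libraries of 1943 here and 5.01 in the fit of the WT response. Ribosomal protein genes fell in 2 of 37 cases (2 adjusted over the list alone, set test adjusted p 0.00373, and adjusted p = 0.0602 with a correlation preset to 0.05). The set test did not pass for mitosis and G2/M genes (0 rose, 3 fell of 30, adjusted p 0.0916) or mitochondrially encoded genes (0 rose, 0 fell of 13, adjusted p 0.289). The BCL2 family did not pass either (1 rose, 2 fell of 14, adjusted p 0.955), with a median of 0.039 and a set test pointing down. Fibroblast (1 rose of 9, adjusted p 0.490), leukocyte (3 rose of 8, adjusted p 0.231) and endothelial markers (2 rose of 7, adjusted p 0.0701) did not pass.

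Over all genes, 3358 rose and 2350 fell in KO cells among 26924 tested, from the authors' deposited table. The largest rises included the epididymal secretory protein gene WFDC2 (7.92, SE 1.45) and CXCL5 (6.03, SE 0.53), and the largest falls BAHCC1 (-4.64, SE 0.32) and CYP2W1 (-3.91, SE 0.28), in the authors' deposited table. The untreated KO libraries carry a different growth text in the labels from the other groups, so a batch cannot be told apart from this group. Of the changed genes, 58.8% rose as deposited, 67.5% after folds were centred on the median gene, 67.7% after a correction for GC content and 44.9% among genes at or above the median mean. At an adjusted p under 0.01, 3513 genes changed.

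**Figure D2:**
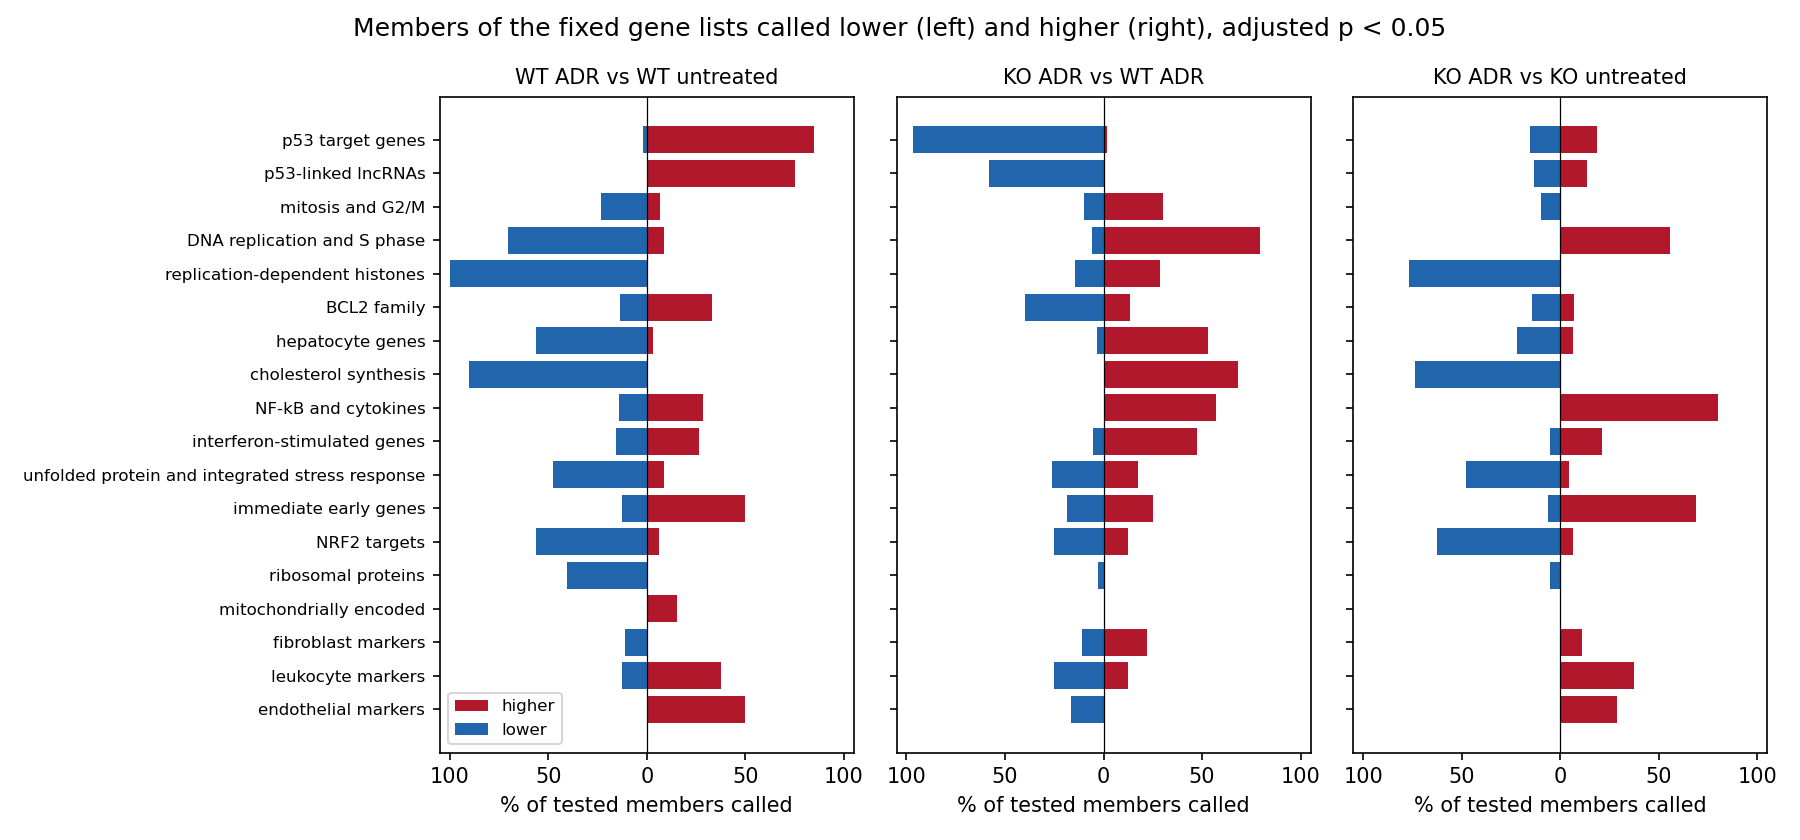
Percent of the tested members of each fixed gene list called higher (red, to the right) and lower (blue, to the left) at an adjusted p under 0.05 in the authors' deposited tables, 1 panel per comparison. DNA replication genes fell in 24 of 34 cases in WT and rose in 19 of 34 in KO cells.

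The title of the study concerns p53-inducible lncRNAs, which here were genes that rose with ADR in WT cells and were lower in treated KO than in treated WT cells. By that rule 422 lncRNAs were called among 5349 tested in both of the authors' deposited tables, or 44.6% of the 947 that rose, where independent lists would share 106.4. The count was 187 among genes at or above the median mean and 123 at a mean of at least 100. They comprised 185 lincRNAs, 143 antisense RNAs, 48 sense intronic, 12 sense overlapping and 34 processed transcripts. The deposited type processed transcript is also given to UHRF1, which encodes a protein, so these counts of lncRNAs can include protein-coding genes. The largest rise was that of RP3-337O18.9 (ENSG00000271984.1; chromosome 20, 44521333 to 44522058 on the minus strand in GRCh37), an antisense RNA with 569 bases of exons, at 8.41 (SE 0.44, adjusted p 6.59e-78) in the authors' deposited table. It was lower in treated KO cells by -7.76 (SE 0.37) and its KO response was 2.23 (SE 0.83, adjusted p 0.0379), in the authors' deposited tables. CTD-2561B21.5 (chromosome 17, 78940039 to 78945013), also antisense, had a WT response of 8.27 (SE 0.69), and LINC00469 (chromosome 17, 71745409 to 71824659) had 7.53 (SE 0.68), in the authors' deposited table. RP11-44F14.8 (7.95, SE 0.70) and RP11-44F14.2 (7.75, SE 0.72) are neighbours on the plus strand of chromosome 16, at 53420856 to 53422997 and 53407391 to 53419054 in GRCh37, with values from the authors' deposited table. LINC00622 (7.64, SE 0.69), AP001053.11 (7.59, SE 0.51), whose current symbol is AATBC, and CTD-2377D24.8 (7.68, SE 0.72) completed the 8 with the largest rise in the authors' deposited table. The libraries were strand-specific per the labels, but how strand was used in counting is not given in the sources used here, so antisense and overlapping genes are uncertain. Of 376 of these lncRNAs tested in the table of KO response, 59 also rose there.

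Over all gene types, 2338 of 5281 genes that rose in WT were lower in treated KO cells, against 711.3 for independent lists, and 1699 genes that fell in WT were higher in treated KO cells, against 426.8. The first count was 1415 at a mean of at least 100. Both comparisons use the treated WT libraries. In 100 simulations of unchanged groups that shared those libraries, a mean of 120.5 genes met both criteria at an unadjusted p under 0.05 where 2957 were observed, and the highest count at an adjusted p under 0.05 was 0. Across 12140 genes the covariance of both fold changes was -1.08 against -0.0371 in the simulations, and the correlation -0.754 against -0.499. No gene changed in these simulations, so a count near 0 after adjustment was set by their design. They do not show how many risen genes the shared libraries alone would call lower in KO cells. The tables hold no value per library, so the shared group could not be split, and part of the excess may come from it. Of 2218 such genes tested in the table of KO response, 525 also rose there and 111 fell.

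**Figure D3:**
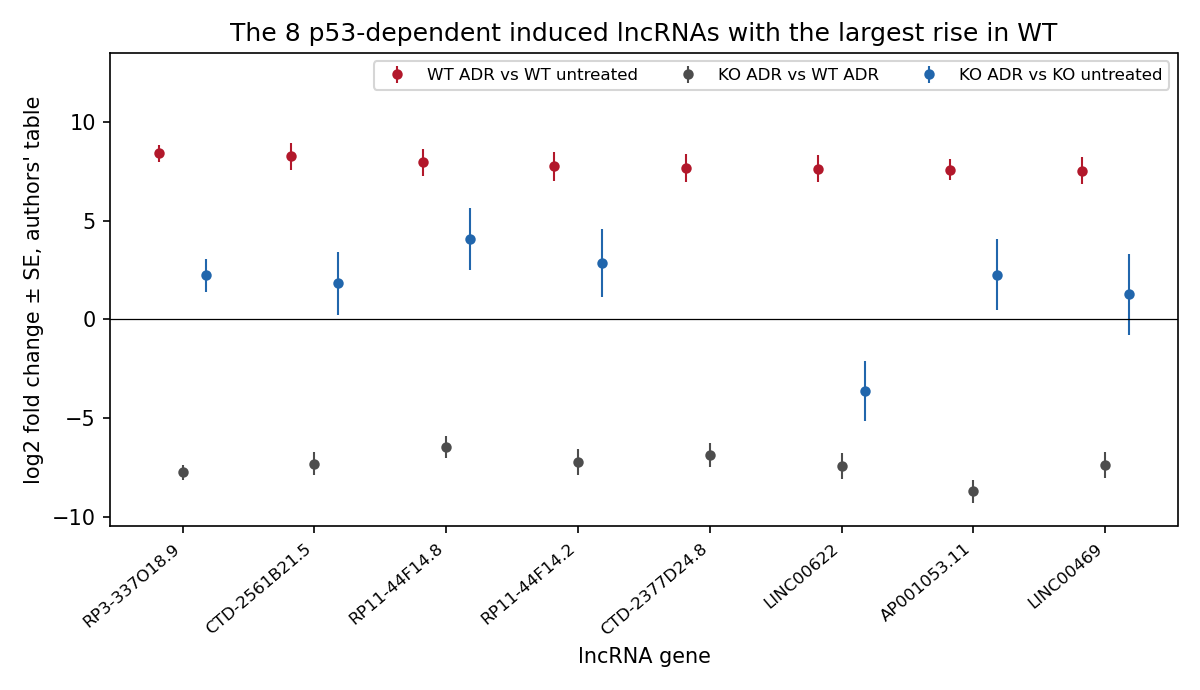
Log2 fold change (points) and SE (bars) in the authors' deposited tables of the 8 p53-dependent induced lncRNAs with the largest rise in WT cells, in the WT response (red), KO against WT under ADR (grey) and the KO response (blue; CTD-2377D24.8 has no value there). WT responses run from 7.53 to 8.41.

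Whether the response to ADR differed between genotypes was tested from the deposited fold changes and SEs. The 11837 genes compared had an adjusted p in both fits and a mean of at least 100 in the fit of the WT response. Of these, 2693 differed at an adjusted p under 0.05. The count was 1736 at an adjusted p under 0.01, 1528 with larger standard errors and 1337 at a mean of at least 1000. The response was higher in WT cells for 1329, of which 929 rose in WT, and lower for 1364, of which 987 fell in WT. By list, the WT response exceeded the KO response for p53 target genes (41 of 58 members higher, 0 lower, median difference 1.64, set test adjusted p 3.47e-30) and p53-linked lncRNAs (7 of 9 higher, 0 lower, median 1.75, adjusted p 2.64e-06). It lay below the KO response for DNA replication genes (27 of 33 lower, 0 higher, median -1.65, adjusted p 9.06e-21) and NF-kB and cytokine genes (5 of 11 lower, 0 higher, median -1.14, adjusted p 0.00251). The same direction was found for cholesterol synthesis genes (6 of 19 lower, 0 higher, median -0.80, adjusted p 0.00338) and hepatocyte genes (10 of 28 lower, 0 higher, median -0.73, adjusted p 0.00112). With a correlation preset to 0.1, both of these calls ended (adjusted p = 0.0935 for each list). The set test of the difference did not pass for the other lists large enough to test, the closest being mitochondrially encoded genes (median 1.18, adjusted p 0.0550).

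Among single genes, the difference was largest for LCE1C, a late cornified envelope gene (11.68, SE 1.84, adjusted p 1.14e-08), ASPG (10.83, SE 1.90) and TREM2 (9.77, adjusted p 5.89e-20). The KO responses of LCE1C (-3.19, SE 1.70, adjusted p 0.175) and ASPG (-2.61, SE 1.79, adjusted p 0.316) did not pass in the authors' deposited table. Their WT responses, 8.49 and 8.22, were below the 9.34 of TREM2, so the order of these genes rests on imprecise KO responses. The difference was most negative for CXCL5 (-6.10, SE 0.77, adjusted p 4.06e-13), the pseudogene RP11-424C20.2 (-5.17, SE 0.49) and the cytokine signalling suppressor SOCS2 (-4.25, SE 0.42). The mean normalised count of RP11-424C20.2 over all libraries was 799.1 in the fit of the WT response and 169.3 in the fit of the KO response. Its difference of responses is therefore uncertain. E2F1 had a difference of -4.17 (SE 0.41). Across these 11837 genes, which are not independent replicates, both responses correlated with a Pearson r of 0.511 and a Spearman rho of 0.438, and 724 genes rose and 1053 fell in both, against 246.1 and 516.9 for independent lists. The responses come from separate fits with different versions of the gene identifiers, the fold changes of the WT response but not of the KO response were moderated by a prior, and the batch of the untreated KO libraries cannot be told apart from their group. Of 11847 shared genes at a mean of at least 100 in the fit of the WT response, 89.1% had means within 10 percent of each other in both fits.

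**Figure D4:**
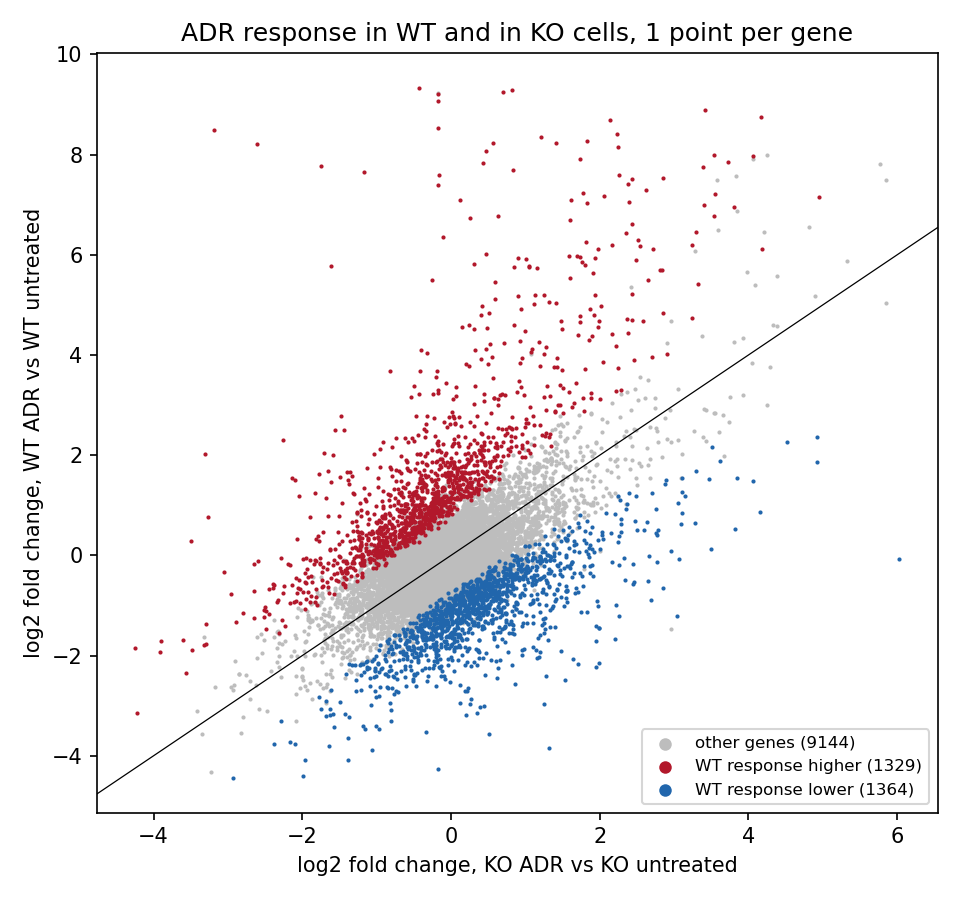
Log2 fold change of the WT response (y axis) against the KO response (x axis) in the authors' deposited tables, 1 point per gene, with the line of equal response. Red marks the 1329 genes with a higher and blue the 1364 genes with a lower response in WT cells, of 11837 compared.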

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

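The tests of deeper sequencing, of a scaling shift and of p53 genotype were chosen only after the results were seen. The other tests of this part were written before their results.

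The response to ADR differed between WT and KO cells for 2693 genes by the test of the difference. By list, the median of WT response minus KO response was 1.64 for p53 target genes, 1.75 for p53-linked lncRNAs, -1.65 for DNA replication genes, -0.73 for hepatocyte genes, -0.80 for cholesterol synthesis and -1.14 for NF-kB and cytokine genes. Among single genes it was 11.68 for LCE1C, 10.83 for ASPG, 9.77 for TREM2, 9.52 for SIGLEC14, 9.39 for CSTA and 9.25 for MUC2. It was -6.10 for CXCL5, -5.17 for RP11-424C20.2, -4.25 for SOCS2, -4.22 for APOL1, -4.17 for E2F1 and -4.13 for TMEM200A. CXCL5 (5.85), RP11-424C20.2 (4.49), SOCS2 (3.12) and E2F1 (3.84) were higher in treated KO than in treated WT cells, in the authors' deposited table. APOL1 did not pass there (-0.50, adjusted p 0.282) and TMEM200A was lower in treated KO cells (-1.02, adjusted p 0.0228). The differences of APOL1 and TMEM200A therefore rest on the untreated cells. A batch of the untreated KO libraries cannot be told apart from their group. RP11-424C20.2, a pseudogene, had a mean normalised count over all libraries of 799.1 in the fit of the WT response and 169.3 in the fit of the KO response.

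DNA replication genes fell in WT and rose in KO cells with ADR. A GC trend of the folds as the whole cause is argued against by the median difference of responses over the 33 members after the trend was taken out, -1.58 (95% bootstrap interval -1.79 to -1.25). A scaling shift is argued against by a median difference of -1.61 relative to the median gene. In the fit that holds both genotypes under ADR, 79.4% of the list was higher in KO cells and 5.88% lower. The treated libraries of this comparison also enter the 2 responses, so it partly restates the pattern and is not an independent test. An effect of the p53 genotype stays a hypothesis found on the same data. A batch of the untreated KO libraries cannot be told apart from their group.

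Genes with little expression were seen in the treated libraries: 4500 genes with 1 read in all libraries together had it in a treated library and 531 in an untreated one, a ratio of 8.47. There were 1101 to 1151 per treated WT library, 1024 to 1224 per treated KO library, 108 to 109 per untreated WT library and 149 to 165 per untreated KO library. Quiet protein-coding genes, with a mean of 2 to 50, also had higher values after ADR. Their median log2 fold change was 1.47 in WT (4543 genes, 1734 rose, 85 fell) and 2.13 in KO cells (4478 genes, 1105 rose, 35 fell). Deeper sequencing is argued against by a ratio of mean size factors, treated over untreated, of 1.09. Transcription past the 3' ends of expressed neighbours is argued against too. The median of quiet genes downstream of such a neighbour minus that of quiet genes beside an expressed gene on the opposite strand was -0.61 in WT (interval -0.87 to -0.36, permutation p 1e-05, the smallest that the permutations can give). Genomic DNA in the treated libraries stays open, since 2.82% of protein-coding genes with at least 3 kb of exons stayed below a mean of 0.5, between the bounds set for and against it. An effect of the drug on transcription was not tested.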

How the results depend on the processing

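No paired analysis was possible because the tables analysed here hold no value per library. The other choices that need such values were not run, namely other scalings, count models and shared dispersion, leaving out each library, the pseudocount and an estimated correlation of list members. Apart from 3 filters on counts of genes (no filter on low counts, the median mean, and a log2 change of 1 or more), of which the first and second also applied to named genes, the alternatives were chosen after seeing the data, those of the gene lists included. Counts of changed genes and of induced genes gave 51 values, of which 43 stayed within 1.5 times the main count. The others were 5549 genes changed in WT at a mean of at least 100, 3513 in KO at an adjusted p under 0.01 and 1415 induced genes at a mean of at least 100. Induced lncRNAs were 187 at or above the median mean and 123 at a mean of at least 100. The difference of responses gave 1337 genes at a mean of at least 1000, 1736 at an adjusted p under 0.01 and 1528 with larger standard errors. Fewer genes were tested at higher means, and for the other counts the threshold was stricter or the error larger. In WT the calls lost at a mean of at least 100 were mostly rises. As deposited 5300 genes rose and 3587 fell, and at that mean 2207 rose and 3342 fell. Of 393 values for 69 list results, 350 kept their direction and side of the threshold, 21 lost and 13 gained it, and 9 reversed, none of them called. Reversed adjusted p were 0.482 (fibroblast markers, WT, ranks), 0.970, 0.688 and 0.980 (histones, KO against WT, centred, GC-corrected and higher mean), 0.990 (NRF2 targets, KO against WT, GC-corrected), 0.997 (endothelial markers, KO against WT, ranks), 0.903 and 0.657 (BCL2 family, KO, centred and higher mean) and 0.923 (interferon-stimulated genes, difference, ranks). With a correlation of 0.1 instead of 0.05, calls also ended for hepatocyte genes in KO (0.16) and, for the difference, hepatocyte and cholesterol genes (0.094). Of 1467 values for 310 named gene results, 1414 kept both, 6 lost and 32 gained the threshold and 15 reversed, none of them called. The reversed log2 fold changes were, centred then GC-corrected, 0.14 and 0.21 for TP53 and 0.13 and 0.30 for DHCR24 in WT. In KO they were 0.016 and 0.16 for AFP, 0.022 and 0.13 for HSP90B1, and 0.043 and 0.16 for LYZ. Centred only, the reversed log2 fold changes were GAS5 in WT 0.047, CXCL5 in WT 0.071, MCM3 in KO 0.055 and BCL2L1 in KO 0.032. GC-corrected only, that of CSTA in KO was 0.084. The cause was not tested.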

Other observations

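Gene families below were chosen after their values were seen. Late cornified envelope genes, structural proteins of skin, rose in WT cells in 5 of 5 tested cases (median log2 fold change 8.49) and were lower in treated KO than treated WT cells in 5 of 5 (median -8.63), in the authors' deposited tables. In the KO response 0 of 5 rose or fell (median -0.18). APOBEC3 genes, which encode cytidine deaminases that act on viral DNA, rose in 6 of 6 cases in WT (median 2.35) and 4 of 6 in KO cells (median 2.09), and 5 of 6 were lower in treated KO cells (median -2.37). Metallothionein genes, which bind metals, fell in 6 of 7 cases in WT (median -1.70) and 7 of 7 in KO cells (median -2.49), and 6 of 7 were higher in treated KO than treated WT cells (median 2.64). Members of these families share near-identical sequence, so single members are uncertain.

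Olfactory receptor genes rose in 7 of 32 and fell in 0 cases in WT cells, and rose in 4 and fell in 6 of 54 in KO cells, at a median mean normalised count of 2.49 in WT. Keratin genes rose in 6 and fell in 1 of 16 cases in WT, and zinc finger genes rose in 83 and fell in 36 of 436. Of all tested genes in WT, 5300 of 27278 rose, and of protein-coding genes with a mean of 2 to 50, 1734 of 4543 rose. The share of zinc finger genes that rose lay near the first of these shares and that of keratin genes near the second. The share of olfactory receptor genes that rose in WT lay between them. No response of these families is read from the counts.

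No table analysed here compares untreated KO with untreated WT cells. Adding the deposited folds of 3 comparisons gives an implied value with no test. Its median over 58 p53 target genes was -0.84, with 51 below 0 and 27 below -1, against a median of 0.013 for all genes with a mean of at least 100. For CDKN1A it was -6.93, for TP53 -2.51 and for MDM2 -1.49. These values join separate fits and share the caveats of the difference of responses.

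The hypothesis that GC-rich genes fell in the KO response did not hold. The bounds for excluding the hypotheses of this paragraph and the next were widened after the values were seen. The original bounds presumed a sign or a pattern shared by both genotypes. Across 11606 genes the rank correlation of GC content and fold change was -0.134 in WT and 0.15 in KO cells. Their difference was 0.284 (95% bootstrap interval 0.264 to 0.304). A GC bias of the untreated KO libraries that lowers GC-rich genes in the KO response would need the opposite sign. A bias in the other direction would give this sign, so a GC bias of those libraries is not excluded. Among the 6504 genes with a mean of at least 1000 the rank correlation in KO cells was 0.146 (interval 0.122 to 0.171). Low counts of GC-rich genes therefore do not account for the trend in KO cells.

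The hypothesis that long genes fall with ADR in both genotypes was tested because doxorubicin, the usual meaning of ADR, is a topoisomerase poison. The rank correlation of genomic length and fold change was 0.026 in WT (interval 0.0085 to 0.045), which argues against it for WT cells. In KO cells the rank correlation was -0.243 (interval -0.260 to -0.224). These intervals resample genes, so they carry no spread between libraries. A batch of the untreated KO libraries cannot be told apart from their group. The median log2 fold change in KO cells was -0.42 for genes over 100 kb and 0.057 for genes under 5 kb.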
